A study of Mus musculus with 11 samples.

How the data were processed

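RNA was measured in the cortex of mouse embryos at stage E14.5 in 3 control and 2 Chd8 conditional knockout libraries. Groups and replicate numbers were taken from the sample titles and genotype labels. The labels do not say whether each library came from a single embryo or a pool. Thus p-values of single loci measure the spread between these libraries only. Per the labels' protocols, total RNA was purified and libraries were made with an Illumina kit. Per the submitters' processing notes, the tools named for the series were CASAVA, TopHat, Cufflinks, Bowtie2 and MACS with the build mm10, without versions or roles. The strand setting and the annotation are not given in the sources used here. The 6 ATAC-seq samples were not analysed here.

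The deposited table gave an FPKM value per locus and library, and the authors' mean FPKM per group, per the file headers. FPKM divides by transcript length and by library size, so a transcript that takes more of a library lowers all others, and it carries no counts. The authors' comparison gave a log2 fold change, a test statistic score, a p-value and a q-value per locus, per the file headers. Calls marked significant by the authors had q-values up to 0.0499. Statements from that comparison name the authors' deposited table, and no error or n is attached to them.

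Sequencing depth is unknown. The lowest FPKM values of the libraries did not fall on whole multiples, and whole reads were not recovered. The commonest ratio of values under 0.05 FPKM placed the depth of control replicate 2 at 1.58 times that of control replicate 1, with 21% of loci within 0.15 log2 units of that ratio, so this is a rough figure. It gave 1.34 for control replicate 3, 1.18 for cKO replicate 1 and 1.04 for cKO replicate 2. The 10 most abundant loci took between 11.4% and 15.4% of the summed FPKM.

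Loci with a mean of at least 1 FPKM over the 5 libraries were kept, values were taken as log2(FPKM + 1), and cKO was compared with control in limma 3.58.1 (R 4.3.3) with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment. The fit had 3 residual degrees of freedom and a prior of 2.49. The libraries were all different (Pearson correlations of 0.880 to 0.933 across loci). The lowest and the highest value were each found between controls, and the cKO libraries had 0.919. On the first principal component (35.6% of the variance), cKO replicates 1 and 2 (-3.35 and -24.89) lay between control replicates 1 (-38.79) and 2 (51.53). On the second (27.1%), they lay above every control, at 16.99 and 40.82. The median log2 change of all tested loci was -0.03. No count-based test was possible without counts.

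Gene lists of cell types, pathways and complexes were written from general knowledge of the developing cortex before the data were examined, as were the tests, the thresholds and the alternatives listed below. The 29 lists with at least 5 tested loci were tested with camera at an inter-gene correlation of 0.01, with adjustment over the lists. They were tested again with the correlation estimated. At the fixed correlation, camera's p-value rests on the spread across loci and does not measure the spread between libraries. No list was called with an estimated correlation. The estimate was 0.032 for microglia and 0.018 for p53 targets, near the fixed value. It was 0.308 for the ventral telencephalon and 0.518 for intermediate progenitors. The test with an estimate also rests on the 3 residual degrees of freedom of the fit, so a lost call is not by itself a sign of a high correlation. Each member also has an adjusted p over its list alone. Named genes were Chd8, up to 10 rises and 10 falls with the largest change among loci at an adjusted p under 0.05 with no overlap between groups, and up to 4 members of each list with the smallest unadjusted p. Other genes are named as examples chosen after their values were seen. These are Csf1r, Cx3cr1, Cdkn1a, Gadd45a, Mdm2, Bbc3, Eed, Tac1, Irx1, Barhl1, Rpl34 and Rpl29. The Hox and mitochondrial genome lists had no tested locus, and the sex-linked list was used to read the sex of the libraries.

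Locus types, lengths and coordinates came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, matched by symbol for 12084 of 12672 tested loci. Several symbols were joined at 355 loci, and their values cannot be assigned to a single gene.

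The procedure was tested on data simulated from the mean and spread of the 12672 tested loci with 3 and 2 libraries. With changes made on FPKM + 1, it called 24% of 100 loci changed by 2-fold and 68% of 100 loci changed by 4-fold. None was called in the wrong direction, and 5 unchanged loci were called. At low loci these changes are larger in FPKM itself, so the shares overstate what was detectable there. A list raised by simulation was called, and no other list was. The simulated noise was drawn independently for each locus. The lack of other list calls therefore does not cover lists whose members vary together, such as the diencephalon list (estimated correlation 0.895). The alternatives were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a variance prior without trend or with robust estimation, leaving out each library, the replicate number as a block, a minimum change of 1.5-fold and the estimated correlation. A fit of protein-coding loci alone, a fit with sex as a term and list tests without Chd8 were added after seeing the data. A test on counts was conditional on a table of counts and was not run.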

Results

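The study measured RNA from the cortex of mouse embryos at stage E14.5, an embryonic age at which the cortical wall holds dividing radial glia, intermediate progenitors and newly formed neurons. Chd8, which encodes a chromatin remodelling enzyme of the CHD family and is a high-confidence autism risk gene, was deleted with Emx1-Cre, a recombinase driver active in dorsal telencephalic progenitors and their progeny. The expression data held 2 conditional knockout (cKO) libraries, labelled with both floxed alleles and Emx1-Cre, and 3 control libraries, whose labels carried floxed alleles and no Cre. Control replicate 1 was labelled Chd8 c/+, and control replicates 2 and 3 were labelled c/c. The series also listed 6 ATAC-seq samples of sorted progenitors in 3 groups of 2, which were not analysed here. Expression was given as FPKM for 24138 loci, of which 12672 reached a mean of 1 FPKM and were tested. FPKM summed to between 418191 and 484296 per library, and between 12237 and 12717 loci reached 1 FPKM in a library. Unless stated otherwise, values below are the mean FPKM ± SD of the cKO (n = 2) against that of the controls (n = 3), and log2 changes are cKO minus control on the log2(FPKM + 1) scale, which understates the change of low genes.

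The comparison of cKO with control asks which transcripts change in the embryonic cortex when Chd8 is lost from the dorsal lineage. Chd8 RNA (locus XLOC_006637; chromosome 14, 52198151 to 52258042 in GRCm38) was 17.2 ± 2.96 against 31.1 ± 0.937, or 55.2% of the control mean. The library values were 31.5, 30.02 and 31.8 in controls 1 to 3 and 19.3 and 15.1 in cKO 1 and 2, so both cKO libraries lay below every control. Microglial genes such as Lyz2, p53 target genes such as Cdkn1a and ventral telencephalic genes such as Dlx2 were higher in the cKO as groups (camera adjusted p = 5.6e-15, 7.8e-06 and 1.1e-07). Genes of intermediate progenitors such as Neurog1 and Eomes, and the Notch pathway genes, were lower as groups (camera adjusted p = 0.00115 and 0.00787). At a mean of at least 1 FPKM, no protein-coding locus passed the test over all loci with all 5 libraries. These statements therefore rest on gene lists fixed before the data were examined, and none of the list calls held with an estimated inter-gene correlation.

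The log2 change of Chd8 was -0.83 (SE 0.15), with an adjusted p of 0.575 over all loci in limma. Adjusted over the list alone, among the 9 members of the CHD family that were tested, Chd8 fell (adjusted p = 0.0155) and was the single member that passed. An exact two-sided permutation test of the library values gave p = 0.1, the smallest value that the 10 splits of 3 and 2 libraries allow. In the authors' deposited table the log2 fold change of Chd8 was -0.86 with a q-value of 0.00331. Chd4, the catalytic subunit of the NuRD complex, was 75.998 ± 24.1 against 122 ± 8.21, and Chd7, the gene mutated in CHARGE syndrome, was 10.9 ± 0.365 against 15.6 ± 1.52. Neither passed when adjusted over the list alone (adjusted p = 0.0631 for Chd4 and 0.0628 for Chd7). The list as a whole was lower by camera, limma's competitive gene set test (median log2 change -0.23, adjusted p = 0.0233). The call was lost with an estimated correlation (adjusted p = 0.634) and without control replicate 1 (adjusted p = 0.172, range over the alternatives at the fixed correlation 0.00725 to 0.172). With Chd8 itself left out, a choice made after seeing the data, the other 8 members were not called (median log2 change -0.20, adjusted p = 0.0833). The median of the full list was -0.39 without control replicate 2, -0.37 without cKO replicate 1 and -0.15 without cKO replicate 2. A protocol field of the expression samples speaks of an Eed knockout, while titles and genotypes name Chd8. Eed, a core subunit of Polycomb repressive complex 2, was 18.6 ± 0.662 against 19.9 ± 1.74, with a log2 change of -0.09 (SE 0.13).

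**Figure D1:**
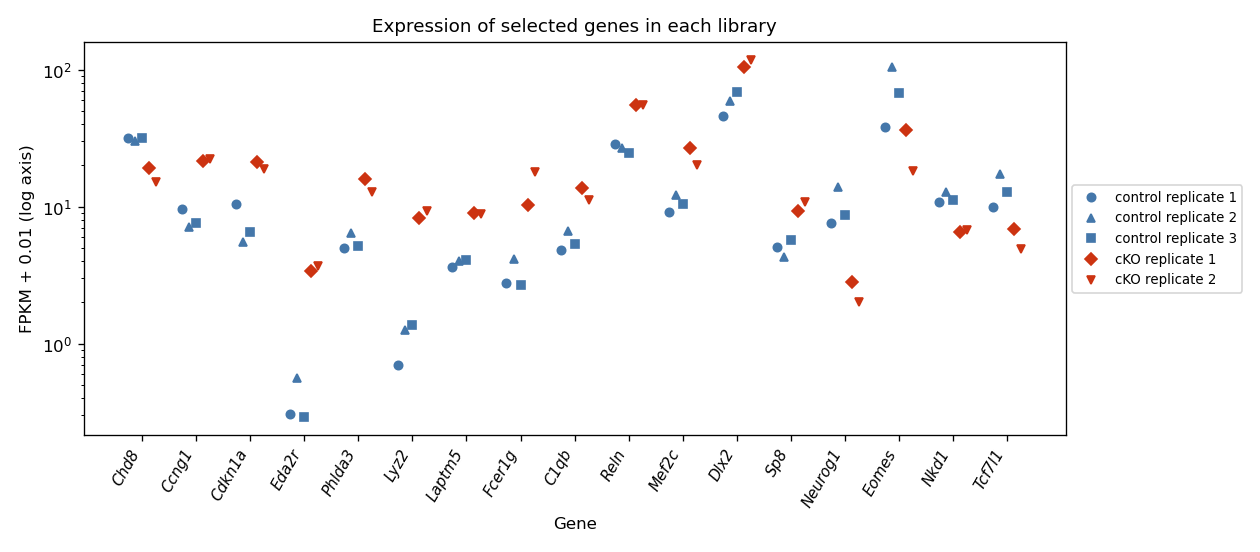
FPKM plus 0.01 on a log axis for 17 genes in each of the 5 libraries, with controls in blue and cKO in red and a marker shape for each library. Both Chd8 values of the cKO, 19.3 and 15.1 FPKM, lie below the lowest control value of 30.02 FPKM, and both Lyz2 and Ccng1 values of the cKO lie above every control.

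Genes of microglia, the resident phagocytes of the brain, were higher in the cKO as a group. The list was called higher by camera (adjusted p = 5.6e-15), and with an estimated correlation it was not (adjusted p = 0.156). All 16 tested members had a positive log2 change, with a median of 0.84, and in 14 of them both cKO libraries exceeded every control, where chance gives 10%. Adjusted over the list alone, 12 members rose, none fell and 4 did not pass. Lyz2, which encodes a lysozyme of myeloid cells (chromosome 10, 117277541 to 117282272), was 8.79 ± 0.705 against 1.10 ± 0.363 (adjusted p = 0.00123 over the list alone, 0.131 over all loci). Fcer1g, a signalling adaptor of Fc receptors, was 14.1 ± 5.51 against 3.20 ± 0.840, and Laptm5, a lysosomal membrane protein of hematopoietic cells, was 8.86 ± 0.0960 against 3.89 ± 0.266. C1qb, a chain of complement component C1q, was 12.4 ± 1.85 against 5.61 ± 0.928. The receptor gene Csf1r, on which microglia depend for survival, was 6.28 ± 0.120 against 3.63 ± 0.573 (adjusted p = 0.0156 over the list alone). Cx3cr1, the fractalkine receptor, did not pass, at 1.92, 2.51 and 1.90 in controls 1 to 3 and 4.58 and 0.875 in cKO 1 and 2. Over all loci no member passed.

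Genes of other non-neural cells showed smaller shifts. The 18 genes of vascular cells had a median log2 change of 0.01 and the 8 loci of erythroid cells one of 0.05, and neither list was called (adjusted p = 0.398 and 0.522). Rgs5, a pericyte gene, was 23.4 ± 5.71 against 13.5 ± 2.24 and did not pass over its list (adjusted p = 0.259). Alas2, the erythroid enzyme of heme synthesis, was 8.98 ± 1.33 against 7.68 ± 1.16. The 9 genes of the meninges had a median of 0.06 (adjusted p = 0.958).

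Targets of the transcription factor p53 were higher in the cKO as a group. Camera gave an adjusted p of 7.8e-06, and the call was lost with an estimated correlation (adjusted p = 0.295). Of the 33 members tested, 9 rose, 1 fell and 23 did not pass when adjusted over the list alone, and the median log2 change was 0.32. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), was 19.98 ± 1.46 against 7.51 ± 2.60 (adjusted p = 0.0152 over the list alone). Ccng1, which encodes cyclin G1 (chromosome 11, 40748552 to 40755309), was 21.99 ± 0.490 against 8.07 ± 1.35, or 2.72 times the control mean (adjusted p = 0.00487 over the list alone, 0.314 over all loci). Eda2r, a receptor of the tumour necrosis factor family (chromosome X, 97333837 to 97377234), was 3.52 ± 0.209 against 0.377 ± 0.155, and Phlda3, an inhibitor of Akt (chromosome 1, 135766085 to 135769134), was 14.3 ± 2.13 against 5.52 ± 0.780. Sesn2, a stress-induced regulator of mTORC1 signalling, was 6.16 ± 0.546 against 2.99 ± 0.0325. Gadd45a, a growth arrest gene, was the member that fell, at 3.32 ± 1.16 against 6.26 ± 0.442 (adjusted p = 0.0449 over the list alone). Mdm2, which encodes the ubiquitin ligase of p53, was 30.7 ± 2.52 against 24.3 ± 1.33, and the proapoptotic gene Bbc3 was 7.69 ± 4.02 against 8.61 ± 1.07, and neither passed.

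Lists of other damage and death genes were not called at a mean of at least 1 FPKM. The 29 genes of the DNA damage response had a median log2 change of 0.01 and none passed over the list (camera adjusted p = 0.522). The 15 apoptosis effectors had a median of 0.08 (adjusted p = 0.135), and were called higher without a filter on low values (adjusted p = 0.0105). Their median was 0.14 without cKO replicate 1 and 0.15 without cKO replicate 2, and their mean went from 0.07 to 0.02 without cKO replicate 1.

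Genes of the ventral telencephalon, the source of cortical interneurons and of the striatum, were higher in the cKO as a group. The list was called by camera (adjusted p = 1.1e-07), and the call was lost with an estimated correlation (adjusted p = 0.634). The 26 tested members had a median log2 change of 0.77 and a mean of 0.64, and without control replicate 2, the lowest library, the mean was 0.35. Adjusted over the list alone 7 rose, none fell and 19 did not pass. Dlx2, a homeobox gene of ventral progenitors, was 110.4 ± 9.26 against 57.7 ± 11.2, and Dlx6os1, a long noncoding RNA of the Dlx5 and Dlx6 locus, was 50.5 ± 9.74 against 21.2 ± 4.85. Sp8, a zinc finger factor of interneuron precursors, was 10.04 ± 0.983 against 5.01 ± 0.715, and Gsx2, a homeobox gene of the lateral ganglionic eminence, was 11.3 ± 0.350 against 7.32 ± 0.546. Adjusted p over the list alone was 0.0298 for Sp8 and 0.0303 for Dlx2. Whether Dlx6os1 shares reads with Dlx5 and Dlx6 was not tested. Striatal genes varied among the controls themselves. Tac1, the substance P precursor, was 19.4, 1.95 and 19.2 in controls 1 to 3 and 34.9 and 26.7 in cKO 1 and 2.

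**Figure D2:**
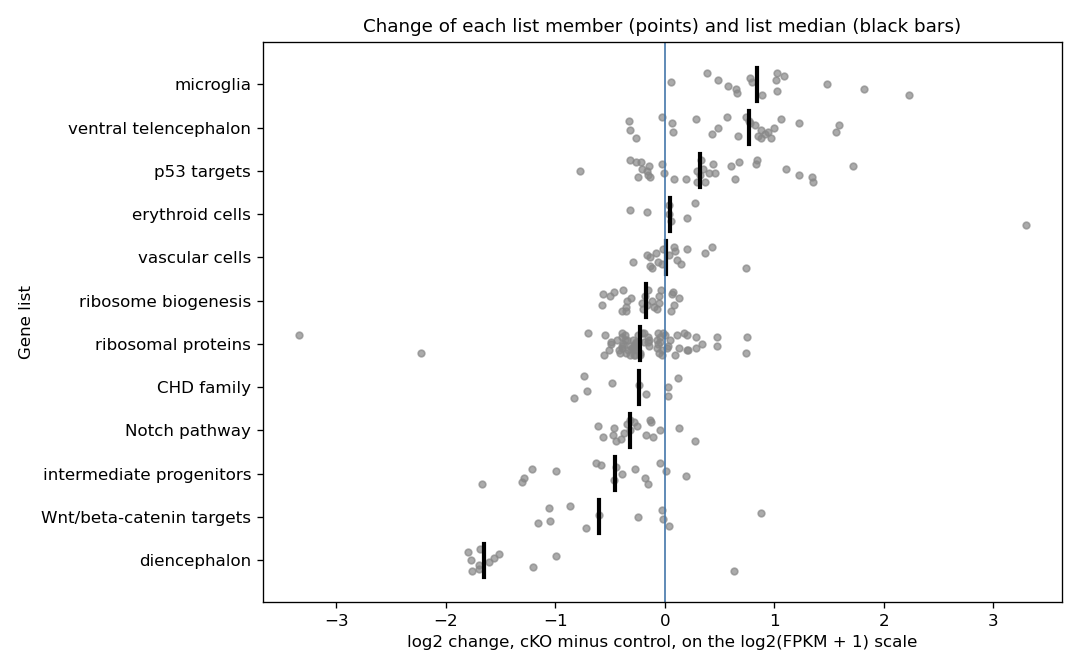
Log2 change of each tested member of 12 gene lists (points), cKO minus control on the log2(FPKM + 1) scale, with the median of each list as a black bar. The microglia list has the highest median, 0.84, and the diencephalon list the lowest, -1.65. The erythroid point at 3.30 is an alpha globin locus whose reads can be split with its near-identical copy.

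Genes of intermediate progenitors, the transit-amplifying cells that give rise to most cortical projection neurons, were lower in the cKO as a group. Camera gave an adjusted p of 0.00115, or an adjusted p of 0.844 with an estimated correlation, at which the call was lost. Of the 16 members tested, 14 had a negative log2 change, with a median of -0.46 and a mean of -0.59. Without control replicate 2, the highest library, the mean was -0.37. Adjusted over the list alone, Neurog1 fell (adjusted p = 0.0225) and the other 15 did not pass. Neurog1, a proneural transcription factor (chromosome 13, 56250478 to 56252180), was 2.41 ± 0.565 against 10.1 ± 3.44, or 0.239 times the control mean. Eomes, which encodes the intermediate progenitor factor Tbr2 (chromosome 9, 118478186 to 118486132), was 37.9, 104 and 67.7 in controls 1 to 3 and 36.5 and 18.3 in cKO 1 and 2, so cKO replicate 1 lay within 2 FPKM of control replicate 1. Neurog2, a proneural factor of the dorsal telencephalon, was 67.4, 166 and 109 in controls 1 to 3 and 58.3 and 35.8 in cKO 1 and 2.

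Radial glial genes did not pass as a list (25 genes, median log2 change -0.22, adjusted p = 0.142) and no member passed over the list alone. Without control replicate 1 the list was called lower (median -0.37, adjusted p = 0.0111), while its median was -0.02 without control replicate 2 (adjusted p = 0.864) and -0.13 without cKO replicate 1 (adjusted p = 0.559). Nes, the intermediate filament gene of neural stem cells, was 47.8 ± 10.6 against 86.99 ± 20.2, and Emx2, a homeobox gene of the dorsal telencephalon, was 13.7 ± 6.06 against 26.6 ± 5.41. The Notch pathway, which maintains progenitors, was called lower (19 genes, 17 with a negative change, median -0.31, adjusted p = 0.00787). The call was lost with an estimated correlation (adjusted p = 0.684) and without cKO replicate 1 (adjusted p = 0.397, range over the alternatives at the fixed correlation 6.4e-05 to 0.397), and the median was -0.15 without control replicate 2. None of its members passed over the list alone. Hes1, a transcriptional effector of Notch, was 15.8 ± 1.25 against 22.5 ± 3.43, and Notch3 was 8.76 ± 0.162 against 12.3 ± 1.47.

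Wnt/beta-catenin targets were called lower (11 genes, median log2 change -0.60, adjusted p = 0.0481). With an estimated correlation the call was lost (adjusted p = 0.634). Adjusted over the list alone, 2 fell, 1 rose and 8 did not pass. Nkd1, a feedback inhibitor of Wnt signalling (chromosome 8, 88521342 to 88594887), fell to 6.66 ± 0.125 against 11.7 ± 1.05 (adjusted p = 0.0118 over the list alone), and Tcf7l1, a repressor of Wnt target genes, fell to 5.87 ± 1.41 against 13.4 ± 3.78 (adjusted p = 0.0331 over the list alone). The member that rose was Sp8, which the ventral telencephalon list also holds. Axin2, a negative feedback component of the pathway, was 6.40 ± 1.99 against 12.4 ± 2.86 and did not pass (adjusted p = 0.0538 over the list alone). The list call was also lost without control replicate 1 (median -0.435, adjusted p = 0.125), without cKO replicate 1 (median -0.702) and without cKO replicate 2 (median -0.497). It was lost as well without a filter (adjusted p = 0.0570), with a mean of at least 5 FPKM (0.0606) and with Chd8 taken out of the other lists (0.0535).

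Ribosomal protein genes were called lower as a list (73 loci, 55 with a negative change, median log2 change -0.23, adjusted p = 0.00922), as were genes of ribosome biogenesis (26 genes, median -0.17, adjusted p = 0.0233). Both calls were lost with an estimated correlation (adjusted p = 0.844 for each list). No member of either list passed over its list alone. Polr1a, the largest subunit of RNA polymerase I, was 7.23 ± 1.10 against 9.75 ± 0.695. Rpl34 was 303, 478 and 369.9 in controls 1 to 3 and 297 and 3.66 in cKO 1 and 2. Ribosomal protein genes have many processed pseudogenes that share reads with them, so single values are uncertain. The median log2 change of ribosomal proteins was -0.36 without control replicate 1 and -0.13 without control replicate 2, and that of ribosome biogenesis -0.27 and -0.11. Without control replicate 2 the adjusted p was 0.300 for ribosomal proteins and 0.248 for ribosome biogenesis, and without control replicate 3 it was 0.0566 and 0.0707. The ribosomal protein call was also lost without cKO replicate 1 (adjusted p = 0.346, range over the alternatives at the fixed correlation 2.3e-06 to 0.346) and the ribosome biogenesis call without cKO replicate 2 (adjusted p = 0.0541, range over the alternatives at the fixed correlation 4.7e-04 to 0.248) and with the replicate number as a block (0.104).

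Neuronal genes moved in both directions. Reln, the extracellular signal of Cajal-Retzius cells (chromosome 5, 21884454 to 22344705), rose to 54.95 ± 0.0644 against 26.9 ± 2.05, adjusted over the list alone (adjusted p = 0.00385 over the Cajal-Retzius list, 0.0190 over the autism risk genes and 0.339 over all loci). It was the single member of each list that passed. Mef2c, a transcription factor gene of the upper-layer list (chromosome 13, 83504017 to 83667079), rose to 23.5 ± 4.85 against 10.6 ± 1.55, and Mdga1, a cell adhesion gene of the same list, fell to 10.9 ± 1.54 against 22.2 ± 4.31 (adjusted p = 0.0251 and 0.0298, adjusted over the list alone). Values of whole cortex do not show which cells carried the rise of Mef2c. Nxph4, a neurexophilin of deep-layer and subplate neurons, fell to 14.7 ± 0.811 against 38.9 ± 10.9, adjusted over the list alone (adjusted p = 0.0467). Tbr1, a transcription factor of early-born neurons, was 136 ± 2.03 against 93.7 ± 27.7 and did not pass. Median log2 changes were 0.18 for 16 deep-layer genes, -0.24 for 14 upper-layer genes, -0.07 for 12 Cajal-Retzius genes, 0.01 for 23 pan-neuronal genes and -0.01 for 59 autism risk genes. None of these lists was called by camera (adjusted p = 0.366, 0.335, 0.341, 0.341 and 0.505). Camera's direction was higher for the Cajal-Retzius and autism risk lists, whose medians were below 0, and for the deep-layer list, whose mean was -0.001. The Cajal-Retzius list was called higher without control replicate 1 (adjusted p = 0.00917), the upper-layer list lower without cKO replicate 1 (0.0455) and the pan-neuronal list higher without cKO replicate 2 (0.00404). Their medians on leaving out other libraries went to -0.55 for Cajal-Retzius genes without control replicate 2, 0.07 for upper-layer genes without cKO replicate 2 and -0.29 for pan-neuronal genes without cKO replicate 1.

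The remaining lists were not called. G1/S genes (30 genes, median log2 change 0.09, adjusted p = 0.0569) and G2/M genes (30 genes, median 0.08, adjusted p = 0.0734) had no member that passed over its list. Ccne2, a cyclin of S phase entry, was 7.19 ± 1.79 against 4.36 ± 0.352. Replication-dependent histones (38 genes, median -0.25, adjusted p = 0.0537) and choroid plexus and hem genes (8 genes, median -0.65, adjusted p = 0.0528) lay on the lower side. The histone genes are near-identical copies without poly(A) tails, so their single values are uncertain. Oligodendrocyte precursor genes (8 genes) had a median of 0.25 (adjusted p = 0.133), and Olig2 was 17.6 ± 3.24 against 10.4 ± 3.39. The list was called higher without a filter on low values (adjusted p = 0.0449), while its median was 0.06 without control replicate 2, 0.12 without cKO replicate 1 and 0.40 without control replicate 1. The 10 genes of Polycomb repressive complex 2 had a median of 0.10 (adjusted p = 0.546), or 0.04 without control replicate 1, 0.04 without control replicate 2 and 0.05 without cKO replicate 2. Stress and ER response genes (16 genes, median -0.01, adjusted p = 0.926) and immediate early genes (10 genes, median -0.07, adjusted p = 0.926) had 1 member that passed over its list between them, Sesn2, which the p53 target list also holds. Camera's direction was higher for the stress and ER response list, whose median was below 0, and for the meninges, whose mean was -0.16. Both cell cycle lists were called higher without control replicate 2, control replicate 3 or cKO replicate 1 (adjusted p at most 0.0182) and lay on the lower side without control replicate 1. Histones were called lower without control replicate 1 (adjusted p = 6.9e-06) and had a median of 0.06 without control replicate 2. Choroid plexus and hem genes were called lower without control replicate 1, control replicate 3 or cKO replicate 2 (adjusted p at most 0.0296), and without cKO replicate 1 their median was -0.15 (adjusted p = 0.559).

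Over all 12672 tested loci, limma called 2 loci higher and 4 lower in the cKO at an adjusted p under 0.05, and each was a short RNA listed at 0 FPKM in every library of a group. The authors' deposited table called none of these loci significant, with q-values from 0.126 to 0.694. The microRNA loci Mir6982 and Mir8112 were listed at 0 in all 3 controls. Mir6982 was 113 and 91.9 FPKM in cKO replicates 1 and 2 (adjusted p = 2.0e-04), and Mir8112 was 23.5 and 26.05 (adjusted p = 0.00122). The small nucleolar RNAs Snora61, Snord55, Snord49a and Snord34, which guide chemical modification of ribosomal RNA, were listed at 0 in both cKO libraries. Snora61 was 269, 237 and 258 FPKM in controls 1 to 3 (adjusted p = 4.7e-05). Snord55 was 81.3, 246 and 146 (adjusted p = 0.0263). Snord49a was 836, 178 and 486, and Snord34 was 169.5, 460.4 and 120.4 (adjusted p = 0.0386 for each). Leaving out 1 library moved these counts: 4 higher and 9 lower without control replicate 2, 10 lower without control replicate 1, 25 higher and 2 lower without cKO replicate 1, and 30 higher without cKO replicate 2.

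Among 299 tested loci shorter than 200 bp, 75.6% were listed at 0 in at least 1 library, against 0.331% of 11785 longer loci. In 8 short loci the zeros filled exactly the cKO or exactly the control group. For the other 9 ways of parting the libraries into 2 and 3, this number was between 5 and 10. Whether the zeros are failed estimates was not tested. The ribosomal protein gene Rpl29 was listed at 0.576, 104 and 88.8 FPKM in controls 1 to 3 and at 26.6 and 0 in cKO 1 and 2. Among 11367 protein-coding loci limma called 0 in the same fit, and 1 without control replicate 2, without cKO replicate 1 or without a filter on low values. At an unadjusted p under 0.05, 390 loci of all kinds were higher and 554 lower, where chance alone gives 634 in all. The total of 944 was 1913 without control replicate 1, 1500 without cKO replicate 1, 629 without control replicate 2, 404 without control replicate 3 and 344 without cKO replicate 2, and 262 with the replicate number as a block and 509 with sex as a term, so it lay below the chance number in several fits. Both cKO libraries exceeded every control at 1699 loci and lay below every control at 1974, where chance gives 10% of the loci for each direction.

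The authors' deposited table called 569 of 13511 loci significant, 163 higher and 406 lower in the cKO. Of the higher loci, 150 had both cKO libraries above every control, and of the lower loci 257 had both below every control, where chance gives 10% of unselected loci for each direction. The largest finite rises in the authors' deposited table among separated, named single genes were those of Gpnmb, a transmembrane glycoprotein of phagocytes (log2 fold change 4.73, q-value 0.0152), Spp1, which encodes osteopontin (3.25, 0.00331), Eda2r (3.22, 0.00331) and Lyz2 (2.998, 0.00331). Gpnmb and Spp1 were chosen after their values were seen. Spp1 was 1.05, 2.60 and 1.83 in controls 1 to 3 and 24.02 and 10.6 in cKO 1 and 2.

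Transcripts of the diencephalon and midbrain, brain regions outside the cortex, were abundant in control replicate 1. The diencephalon list was called lower in the cKO (12 genes, median log2 change -1.65, adjusted p = 0.0481), and no member passed over the list alone. The call was lost with an estimated correlation (adjusted p = 0.844) and without control replicate 1 (median -0.25, adjusted p = 0.163). It was also lost with a mean of at least 5 FPKM (adjusted p = 0.0606) and with Chd8 taken out of the other lists (0.0535). Leaving out cKO replicate 1 or cKO replicate 2 lost the call as well, with 1 cKO library left, though the median stayed at -1.61 in each case. Tcf7l2, a Wnt pathway transcription factor of the thalamus, was 78.5, 2.48 and 11.5 in controls 1 to 3 and 3.36 and 3.98 in cKO 1 and 2. Irx1, a homeobox gene of the thalamus and midbrain, was 34.1, 0.105 and 0.890 in controls 1 to 3 and 0.246 and 0.210 in cKO 1 and 2, and Barhl1 was 30.7, 0.0779 and 0.584 in controls 1 to 3 and 0.166 and 0.0166 in cKO 1 and 2. En2, a homeobox gene of the midbrain and hindbrain border, was 21.4 FPKM in control replicate 1, 0.0284 and 0.0170 in control replicates 2 and 3, and listed at 0 in both cKO libraries. Control replicate 3 held some of these transcripts as well. The mean log2 value of the diencephalon list was 4.55 and 1.28 in controls 1 and 3, and 0.55, 0.73 and 0.75 in control 2 and cKO 1 and 2. Otp, a homeobox gene of the hypothalamus, was 14.9, 0 and 12.1 in controls 1 to 3 and 3.68 and 2.44 in cKO 1 and 2, and Nkx2-4 was 4.92, 0 and 3.15 in controls 1 to 3 and 0 in both cKO libraries. En2, Otp and Nkx2-4 were chosen after their values were seen. Hox genes, which mark the hindbrain and spinal cord, reached at most 0.157 FPKM in any library, over 39 loci.

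Of the 406 loci called lower in the authors' deposited table, control replicate 1 was at least 4-fold above every other library at 48. Control replicate 1 was the highest library at 120 of these loci, control replicate 2 at 276 and control replicate 3 at 10. Among the cKO libraries, replicate 2 was the lowest library at 314 of them and replicate 1 at 44. Recomputed from the library values without control replicate 1, a choice made after seeing the data, 334 of them were at least 1.5-fold lower in the cKO, and 18 were not lower at all. Of the 163 loci called higher in the same table, 160 were at least 1.5-fold higher without that library. At 119 of the 163, cKO replicate 2 was the highest library. The loci were called on the same libraries, so most were likely to keep their fold, and 334 and 160 do not measure robustness.

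**Figure D3:**
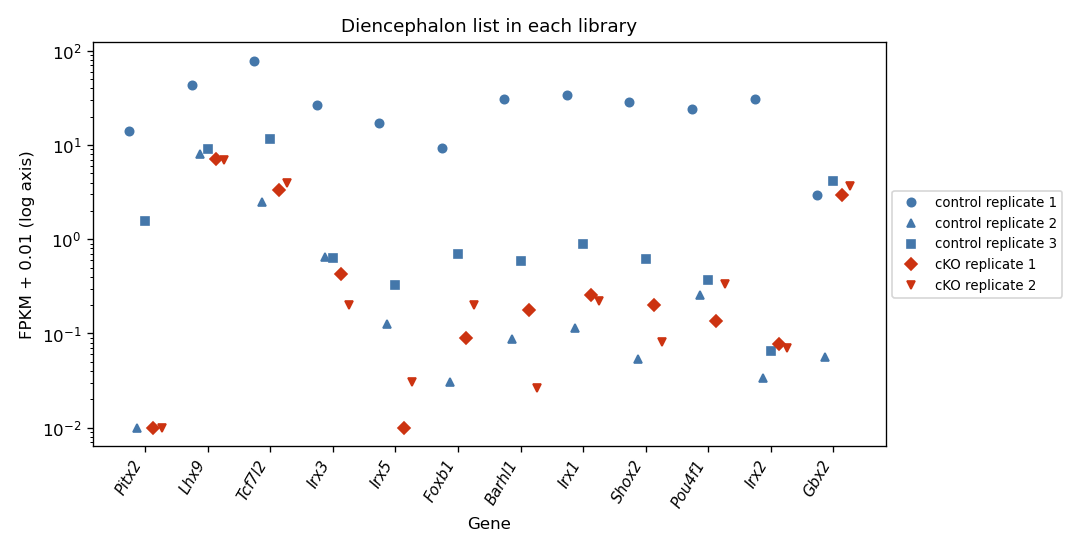
FPKM plus 0.01 on a log axis for the 12 tested genes of the diencephalon list in each library, with controls in blue and cKO in red and a marker shape for each library. Control replicate 1 stands above the other 4 libraries for 11 of the 12 genes, with Tcf7l2 at 78.5 FPKM against 11.5 FPKM or less elsewhere. Gbx2 is the exception.

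The sexes of the libraries differed within both groups. Xist, which is expressed from the inactive X chromosome, was 86.3, 67.4 and 72.3 FPKM in control replicates 1 and 2 and cKO replicate 1, and 0.0585 and 0.0378 in control replicate 3 and cKO replicate 2. The Y-linked gene Eif2s3y was 27.2 and 30.6 FPKM in the latter and listed at 0 in the others.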

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

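The fits of protein-coding loci alone, with sex as a term and with Chd8 taken out of the lists were chosen after seeing the data. Chd8 stayed lower under all 16 alternatives that refit it (log2 change -0.996 to -0.66) and passed over all loci in none. The microglia, ventral telencephalon, p53 target and intermediate progenitor calls held in all 17 alternatives other than the estimated correlation, which left 0 lists called higher and 0 lower. The cause of the changes below was not tested, except that fewer loci or libraries enter some fits.

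The 2 loci called higher became 1 with a pseudocount of 0.01, 1 with a mean of at least 5 FPKM, 1 with the replicate block and 0 among protein-coding loci alone. Leaving out each library gave 2 to 30, with 4 without control replicate 2, 25 without cKO replicate 1 and 30 without cKO replicate 2, where the lone cKO library is assumed to vary like the controls. The 4 loci called lower became 1 without a filter, 2 without a variance trend, 2 with a robust prior, 2 with the replicate block, 0 among protein-coding loci and 1 with sex as a term. Leaving out each library gave 2 to 10, with 10 without control replicate 1, 9 without control replicate 2 and 2 without cKO replicate 1. Lists called higher went from 3 to 5 without a filter and with the replicate block, and were 4 to 5 on leaving out each library. They were 5 without control replicate 2, 3 or cKO replicate 1. Lists called lower, 7 with all libraries, were 4 to 7 on leaving out each library, with 4 without cKO replicate 1. The replicate numbers are not said to mark a shared litter or batch, and same-numbered libraries did not deviate together (correlation of deviations -0.067 for number 1 and -0.109 for number 2, across loci). Under the block the ribosome biogenesis call was lost (adjusted p = 0.104). Wnt target and diencephalon calls were lost with a mean of at least 5 FPKM (adjusted p = 0.0606 for each), and the Wnt target call without a filter (adjusted p = 0.0570).

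With Chd8 taken out of the lists 4 were called lower, and the calls of the CHD family (adjusted p = 0.0833), Wnt targets and the diencephalon (0.0535 for each) were lost. Chd8 is in neither of the latter lists, whose adjusted p moved with the ranks of the other lists. Apoptosis effectors (adjusted p = 0.0105) and oligodendrocyte precursors (0.0449) were the 2 lists added to those called higher without a filter. Choroid plexus and hem genes were called lower without a filter, under both scalings, with the block, among protein-coding loci and with sex as a term (adjusted p at most 0.0439). Replication histones were called lower under both scalings and with the block (adjusted p at most 0.0439). The block also gave calls of G1/S genes (0.00241) and G2/M genes (5.3e-04) as higher and of radial glia (0.0368) as lower, and among protein-coding loci G1/S genes were called higher (0.0485). Lists that were not called changed direction in some fits. The adjusted p after such a change was 0.619 for meninges and 0.818 for immediate early genes without a filter. It was 0.943 for vascular cells and 0.592 for stress and ER response with a mean of at least 5 FPKM. For meninges it was 0.996 with median-of-ratios scaling, 0.914 with quantile normalization and 0.620 with the replicate block, and for immediate early genes 0.975 with sex as a term. Lists that changed direction on leaving out a library had these ranges of adjusted p over the 5 libraries: DNA damage response 0.0867 to 0.654, G1/S genes 1.9e-05 to 0.774, G2/M genes 1.5e-04 to 0.894, meninges 0.233 to 0.724, stress and ER response 0.578 to 0.845, pan-neuronal 0.00404 to 0.877, Cajal-Retzius cells 0.00917 to 0.604, immediate early genes 0.300 to 0.845, replication histones 6.9e-06 to 0.557, deep-layer neurons 0.0527 to 0.876, autism risk genes 0.0541 to 0.906 and upper-layer neurons 0.0455 to 0.568. G1/S and G2/M genes were on the lower side without control replicate 1 (adjusted p = 0.319 and 0.213). They were called higher without control replicate 2, control replicate 3 or cKO replicate 1 (adjusted p at most 0.0148 and 0.0182). Medians of other lists that were not called ranged, on leaving out each library, over -0.03 to 0.14 for the DNA damage response, -0.02 to 0.06 for vascular cells, -0.02 to 0.16 for erythroid cells, -0.25 to 0.16 for meninges, 0.02 to 0.29 for deep-layer neurons, -0.09 to 0.07 for autism risk genes, -0.14 to 0.04 for stress and ER response and -0.20 to 0.15 for immediate early genes. Genes that changed sign on leaving out a library were Col1a2 (log2 change -0.89 to 0.14), Crabp2 (-0.68 to 0.0420) and Hbb-y (-0.25 to 0.81). Cx3cr1 changed sign with pseudocounts of 0.1 (log2 change -0.04) and 0.01 (-0.063) and ranged from -0.72 to 0.85, Bbc3 from -0.71 to 0.27 and Rpl29 from -4.62 to 0.17. A test on counts was not run, since no counts were used here. Depth is unknown, and the loci near the 1 FPKM limit are the least precise.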

Other observations

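All tests of explanations below were chosen after the result was seen, except the counts over other splits for the microglia, p53 target and ventral telencephalon lists. Further genes of phagocytes lay outside the fixed lists and were picked after their values were seen. In the authors' deposited table the log2 fold change was 2.62 for C3ar1, a complement receptor, 2.44 for Cd53, a leukocyte tetraspanin, and 1.72 for Adgre1, the macrophage antigen F4/80. The q-values were 0.00331, 0.00331 and 0.0102. Apoe, a lipid carrier of glia and macrophages, was 75.4 ± 7.69 against 38.6 ± 4.97 FPKM (SD, 2 cKO and 3 control libraries) with an adjusted p of 0.575 over all loci in limma.

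The microglia list was called higher in the cKO, though not with an estimated correlation (adjusted p = 0.156), while the lists of vascular, erythroid and meningeal cells were not called. Blood left in the cKO cortices would raise erythroid transcripts with them, yet the erythroid list had a median log2 change of 0.051 (-0.02 to 0.16 on leaving out each library) and an upper quartile of 0.22, against a median of 0.84 and a lower quartile of 0.64 for microglia. Hbb-b2 was 416 ± 47.7 against 399 ± 41.5 FPKM and Hbb-y 376 ± 187 against 290.2 ± 15.1, while 1 of the 2 loci of Hba-a1 and Hba-a2 had a log2 change of 3.30, brought the list mean to 0.43 and was listed at 0.480, 163 and 0.434 in controls 1 to 3. A smaller share of neural cells would raise vascular transcripts alike, yet the vascular median was 0.013 (-0.02 to 0.06) and its upper quartile 0.14. Lyz2 and Adgre1 are genes of myeloid cells and macrophages at large, so these values do not tell microglia from other macrophages. A larger number of such cells or a change in their state in the cKO stays open as a hypothesis. So does the Cre, which the control labels do not carry, and none of these was tested.

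Control replicate 1 held transcripts of brain regions outside the cortex, and control replicate 3 held some of them (mean log2 value of the diencephalon list 4.55 and 1.28, against 0.55 to 0.75 in the other 3 libraries). In 11 of the 12 tested diencephalon genes control replicate 1 was at least 4-fold above every other library (on FPKM + 1), and 2 of the 12 reached 1 FPKM in all 4 other libraries. Scaling of control replicate 1 is argued against by its median log2 difference from the others, which was 0.022 over all loci and 4.14 over the list. Diencephalic and midbrain tissue in the dissection of control replicate 1 may account for the pattern, with Tcf7l2 at 78.5 and Lhx9 at 42.99 FPKM as its most abundant list members. Within control replicate 1 the Chd8 c/+ genotype cannot be told apart from this, since that library was the only expression library of that genotype (1 library). Its Chd8 RNA was not lower, at 31.5 FPKM against 30.02 and 31.8 in control replicates 2 and 3. Control replicate 3 was labelled c/c, so the c/+ genotype does not account for the transcripts held there.

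The ventral telencephalon list was called higher and the intermediate progenitor list lower in the cKO, and neither call held with an estimated correlation (adjusted p = 0.634 and 0.844). The 8 striatal genes of the list differed among the 3 controls by a median log2 range of 1.41, against 0.37 for random sets of matched expression. Tac1 (19.4, 1.95 and 19.2 in controls 1 to 3) was low in control replicate 2. Zfhx3 (21.3, 1.96 and 5.81), chosen after its values were seen, was highest in control replicate 1. Dissections may have held different amounts of striatum, and the other tissue of control replicate 1 may add to the range. Control replicate 2 also differed from the other controls in lists without striatal genes. Mean log2 values in controls 1 to 3 were 5.475, 6.126 and 5.695 for radial glia and 6.666, 5.983 and 6.335 for pan-neuronal genes. Whether the make-up of control replicate 2 adds to the range was not tested. The median log2 change of the 8 striatal genes in the cKO was 0.36, against 0.87 for the other 18 members. The amount of striatal tissue in each dissection and an effect of the genotype therefore cannot be told apart with 2 cKO libraries. Dilution of the cortical lineage by other tissue cannot be told apart from it either, since 7 genes of dorsal projection neurons had a median log2 change of -0.32 with Tbr1 (0.58) and Tle4 (0.16) above 0, and the deep-layer list had a median of 0.18 with 10 of 16 members above 0 (0.02 without cKO replicate 1, 0.09 without control replicate 2, 0.12 without control replicate 3 and 0.29 without cKO replicate 2). A change of progenitor identity after loss of Chd8 stays open and was not tested.

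The 5 libraries allow 10 splits into 3 and 2, too few for a share under 0.05. For loci called at an adjusted p under 0.05 the real split gave 6 and the highest other 10, and 7 splits reached 6, the real one included. For list medians the real and the highest other absolute values were 0.84 and 0.64 for microglia (1 split as large, the real one), 0.32 and 0.20 for p53 targets (1 split) and 0.77 and 0.78 for the ventral telencephalon (2 splits). The split of control replicates 2 and 3 from the other 3 libraries gave 2283 loci at an unadjusted p under 0.05, against 944 for the real split. It differs from the real split only in placing control replicate 1 with the cKO libraries. The real groups gave 1913 loci without control replicate 1, 629 without control replicate 2 and 404 without control replicate 3. The larger number thus goes with the placing of control replicate 1, and whether other structure of the samples adds to it was not tested.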
